A study of Homo sapiens with 19 samples.

How the data were processed

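Chromatin immunoprecipitation followed by sequencing was carried out on HEK293, HepG2, MCF-7 and IMR90 cells. Per the labels' protocols, cells were cross-linked, chromatin was sheared on a Bioruptor and precipitated with a high-sensitivity ChIP kit from Active Motif, and libraries were made with the NEBNext Ultra II kit and sequenced in paired-end mode on a NovaSeq S4 lane. FLAG-TDG, the catalytic domain of TDG with the N140A mutation and a FLAG tag, was expressed stably from a lentiviral vector and precipitated with the M2 anti-FLAG antibody, and MBD3 was precipitated from untreated cells. Per the submitters' processing notes the tools were bcl2fastq 2.20, Trim Galore 0.6.7, SAMtools 1.16.1, Picard 2.18.29 and MACS2 2.2.7.1 and the genome build was hg38. The aligner is not given in the sources used here.

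The data analysed were 13 deposited peak lists, one per immunoprecipitation, in the narrowPeak format of MACS2. No list pooled replicates. The 6 input libraries were not analysed here, because no peak list belongs to them. In each list the deposited score was checked to be the whole part of 10 times the −log10 q. The deposited ratio is the fold enrichment of the read pileup at the summit over the local background, as the authors' peak caller made it. The caller adds a constant to both, which lowers folds more where the background is low. The deposited −log10 p and −log10 q values are the significance of that enrichment, and the lowest −log10 q of each list corresponds to a threshold of q = 0.05. The other deposited column gives the offset of the summit from the peak start in bp. These values depend on the depth of a library, so folds and −log10 q were used to describe and rank peaks within a list and not to test differences between lists.

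Samples were grouped by the labels into FLAG-TDG in HEK293 (3 replicates), FLAG-TDG in HepG2, MCF-7 and IMR90 (1 each), the anti-FLAG control in HEK293 (1) and MBD3 in HEK293, TDG-knockout HEK293, TDG-N140A HEK293, HepG2, MCF-7 and IMR90 (1 each). The labels do not say that the 3 replicates came from separate cultures, so their spread, given as SD, may be technical, and p-values measure only the spread between these samples. Per the labels 1 input library serves FLAG-TDG and MBD3 in each of HepG2, MCF-7 and IMR90, and each HEK293 FLAG-TDG replicate has its own. The labels name no input for MBD3 or the anti-FLAG control in HEK293.

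Genes came from a RefSeq table of gene spans on hg38 without strands or sequence, which gave 20037 protein-coding genes on 24 chromosomes. The start of a gene could thus not be told from its other end, and the promoter of the original design was replaced by the gene end: a peak was at a gene end when it lay within 1000 bp of either end of a gene. A gene was called in HEK293 FLAG-TDG when at least 2 of the 3 libraries had such a peak, and elsewhere when the single library did. Either end counted, so 2 lists that call a gene may have peaks at opposite ends. Peaks of the HEK293 FLAG-TDG libraries that shared at least 1 bp were merged, and a region was reproducible with peaks from at least 2 libraries. Lists were compared by the share of peaks that overlapped by at least 1 bp. Expected shares came from 1000 random placements of the peaks within their chromosomes, taking the highest annotated or called coordinate as chromosome length, and expected numbers of shared genes from independent lists of the same sizes. Shares from single libraries carry exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only.

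Depth was estimated from the lists themselves. For each peak the pileup and the local background were recovered from the fold and the −log10 p under the Poisson model of the peak caller, which succeeded for 99.9% to 100% of peaks in each list, and the lowest local background was taken as the floor. To compare lists at an equal floor, pileups of the called peaks were thinned at random to the ratio of the floors and called again at the lowest −log10 p of the list with the lower floor, as the mean of 20 draws. Thinned lists used as alternatives were a single draw each. For the lists that have a common input, positions with a common background and no enrichment were simulated (4000000 per pair) and the share called in both was recorded. The recovery was tested on 2000 simulated peaks, of which 100% were given their true pileup, and the overlap count on lists with 30% of peaks planted, where 30.7% were found.

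The line matching of MBD3 and FLAG-TDG was tested by an exact one-sided permutation test over the 24 pairings of 4 MBD3 with 4 FLAG-TDG lists. Its statistic was the mean log2 odds ratio of gene calls, with 0.5 added to each cell, over genes called for FLAG-TDG in some but not all lines, and a version on peak overlap was added after the data were seen. FLAG-TDG and control libraries in HEK293 were compared by an exact two-sided permutation test over 4 splits. The gene-end share of the 3 HEK293 FLAG-TDG libraries was compared with that of each other line in the same way, after the data were seen. Differences between groups of 1 library each, and between lines at single genes, were not tested.

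A set of 21 gene lists was fixed beforehand: NuRD subunits, base excision repair and cytosine oxidation, DNA methylation machinery, cytosolic ribosomal proteins, proteasome, respiratory complex I, DNA replication, immediate early genes, germline genes, imprinted genes, hepatocyte, luminal breast, fibroblast, and lymphoid and myeloid markers, HEK293-associated neural and renal developmental genes, HOX genes, numbered zinc finger genes, replication-dependent histone genes, olfactory receptors, keratin-associated proteins and clustered protocadherins. Each list's share of called genes was placed among 10000 random lists of the same size. The design asked for random lists matched on CpG content, which needs a genome sequence, so they were not matched. Clustered genes that share a peak each counted, so percentiles of clustered lists, such as HOX and histone genes, can be too extreme. The genes named were chosen by a rule fixed beforehand, by the deposited −log10 q of the best gene-end peak: the 10 highest by mean rank among genes called in all 6 FLAG-TDG libraries, the 4 highest per line among genes called in that line alone, the same for MBD3 over 4 lines, the 6 highest in the knockout among genes called there and in TDG-N140A but not in the wild type, the 6 highest in the wild type among genes not called in the knockout, the 5 highest in the control, 2 to 4 members of each list and those not called, and TDG, MBD3, MBD2, CHD4, HDAC1, TET1, TET2 and TET3. Genes that share an end are named together. With MBD3 in all 4 lines there were 9 genes, and all are named.

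Alternatives were a minimum −log10 q of 5, an overlap of at least 50% of the shorter interval, a window of 500 bp, equal numbers of top peaks per list, a call in all 3 HEK293 libraries, removal of peaks that overlap a control peak and leaving out each HEK293 replicate. Equal numbers were set within each comparison by its shortest list, so they differed between comparisons. The alternatives chosen after the data were seen were the thinned HEK293 FLAG-TDG lists, FLAG-TDG peaks of 300 bp round their summits, the thinned knockout list and peaks anywhere in a gene with random lists matched on gene length in 10 bins. Computations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and figures Matplotlib 3.10.9.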

Results

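The data set held 19 human ChIP-seq samples from 4 established cell lines, of which 13 were immunoprecipitations with a peak list and 6 were input libraries. HEK293 is an embryonic kidney line, HepG2 a liver cancer line, MCF-7 a breast cancer line and IMR90 a lung fibroblast line. One set of 6 libraries mapped a FLAG-tagged catalytic domain of thymine DNA glycosylase (TDG) that carries the catalytic mutation N140A, called FLAG-TDG here, with an anti-FLAG antibody. TDG is the base excision repair enzyme that removes thymine from G:T mismatches and oxidised forms of methylcytosine left by the TET enzymes. This set had 3 replicates in HEK293 and 1 library each in HepG2, MCF-7 and IMR90. A control library used the anti-FLAG antibody on HEK293 cells without FLAG-TDG. The second set of 6 libraries mapped endogenous MBD3, a methyl-CpG-binding domain protein and core subunit of the NuRD deacetylase complex, in wild-type HEK293, TDG-knockout HEK293, HEK293 with the TDG N140A mutation, HepG2, MCF-7 and IMR90, with 1 library each. Apart from FLAG-TDG in HEK293 no group had replicates, so all other values come from single libraries.

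The HEK293 FLAG-TDG lists held 26830, 23286 and 25896 peaks, against 7332 in HepG2, 18200 in MCF-7, 21733 in IMR90 and 216 in the anti-FLAG control. The MBD3 lists held 2781 peaks in wild-type HEK293, 10799 in TDG knockout, 4425 in TDG-N140A, 5345 in HepG2, 11487 in MCF-7 and 10574 in IMR90. The lists give no read totals, so depth is known only through the background floor, the lowest local background at any summit of a list, in reads over a position. The floor was 4.70 ± 0.559 (SD, n = 3) in HEK293 FLAG-TDG, 1.61 in HepG2 FLAG-TDG, 1.299 in MCF-7 FLAG-TDG, 1.53 in IMR90 FLAG-TDG and 0.440 in the control. Among the MBD3 lists it was 0.673 in wild-type HEK293, 0.826 in TDG knockout, 0.577 in TDG-N140A, 0.847 in HepG2, 1.24 in MCF-7 and 0.777 in IMR90. The HEK293 FLAG-TDG lists thus had the highest floor and the control the lowest.

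FLAG-TDG in HEK293 was recovered at the ends of most protein-coding genes. A peak in at least 2 of the 3 libraries lay within 1000 bp of an end of 12475 genes, 62.3% of the 20037 annotated. The highest-ranked of the genes called in every FLAG-TDG library was KMT2A, which encodes a histone H3 lysine 4 methyltransferase and spans 118436492 to 118526832 on chromosome 11 (hg38). Its peak had a fold enrichment of 7.84 ± 1.96 (SD, n = 3) over local background, and in the first replicate it ran from 118434536 to 118436639, across one end of the gene. KMT5B, a histone H4 lysine 20 methyltransferase gene at 68154863 to 68213648 on the same chromosome, had a fold of 6.48 ± 1.25. The genes for the proteins under study were themselves called, with folds of 2.52 ± 0.601 at TDG, 2.79 ± 0.494 at MBD3, 3.62 ± 1.3 at its paralogue MBD2, 2.36 ± 0.357 at the NuRD remodeller gene CHD4 and 3.01 ± 0.971 at the deacetylase gene HDAC1. The cytosine dioxygenase genes TET1, TET2 and TET3 had folds of 2.58 ± 0.428, 2.88 ± 0.261 and 3.46 ± 0.496.

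The 3 HEK293 libraries together covered 36995 regions, of which 21962 (59.4%) were found in at least 2 libraries and 15623 (42.2%) in all 3. Between any pair of libraries 66.9% to 77.6% of peaks overlapped. Peaks of the reproducible regions had a median −log10 q of 9.95 ± 2.01 (SD, n = 3) against 4.57 ± 0.505 for the other peaks. Reproducibility went with position, since 63.4% of the regions found in all 3 libraries, 51.6% of those in at least 2 and 8.36% of those in 1 lay at a gene end. A reproducible region lay at one end only of 11681 genes and at both ends of 831, so that 93.4% of these genes had it at one end.

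Very little of this signal was present without FLAG-TDG. The anti-FLAG control had a peak at 10 genes, the top of which was CNIH4 (fold 12.8), followed by HDX (7.67), the uncharacterised LOC101929627 (5.63), NBPF14 (5.35) and the shared end of CEACAM19 and the poliovirus receptor gene PVR (4.96). A control peak overlapped 56 of the 21962 reproducible regions, or 0.255% (exact binomial 95% interval 0.193 to 0.331), while 58 of the 216 control peaks (26.9%, interval 21.1 to 33.3) fell in such regions. FLAG-TDG and control differed in number of peaks (25337 ± 1837, SD, n = 3, against 216) and in the share at gene ends (45.2 ± 1.79% against 5.08%), each by far more than the replicate spread. An exact two-sided permutation test of 3 libraries against 1 gave p = 0.25 for both measures, also after Benjamini-Hochberg adjustment, and 0.25 is the smallest p that this design allows. The control also had the lowest floor; when pileups of the HEK293 FLAG-TDG peaks were thinned to its floor, 1534 ± 813 (SD, n = 3) peaks were left, and 60.5% of these lay at a gene end.

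The association with gene ends differed in size between the cell lines. In HEK293 45.2 ± 1.79% of FLAG-TDG peaks lay at a gene end, 12.2 ± 0.620 times the 3.70% of randomly placed peaks, while 26.7 ± 1.17% lay inside genes only and 28.2 ± 0.770% outside genes. The share at gene ends was 9.02% in MCF-7 (exact binomial 95% interval 8.60 to 9.45), 6.0% in IMR90 (5.69 to 6.33) and 4.37% in HepG2 (3.91 to 4.87), which was 3.20, 2.13 and 1.56 times random placement. All 3 shares were below the HEK293 value by many times its replicate SD. HEK293 peaks were also wider, with a median of 638 ± 5.51 bp (SD, n = 3) against 289 bp in HepG2, 253 bp in MCF-7 and 313 bp in IMR90. An exact two-sided permutation test of the share in the 3 HEK293 libraries against the 1 of each other line gave p = 0.25 for all 3 lines, also after Benjamini-Hochberg adjustment, the smallest p that 3 libraries against 1 allow. The median local background under the peaks was 4.98 ± 0.484 times the floor in HEK293 (SD, n = 3), 1.39 in MCF-7, 1.09 in IMR90 and 1.03 in HepG2. HEK293 peaks with a background of at least 2 times the floor lay at a gene end in 54.7 ± 2.57% of cases and the rest in 4.47 ± 1.01% (SD, n = 3), against 19.7% and 2.39% in MCF-7, 15.7% and 2.96% in IMR90 and 9.40% and 3.25% in HepG2. The HEK293 libraries had shortest peaks of 304 to 328 bp and the other 10 lists of 186 to 221 bp, so line and library preparation cannot be told apart.

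**Figure D1:**
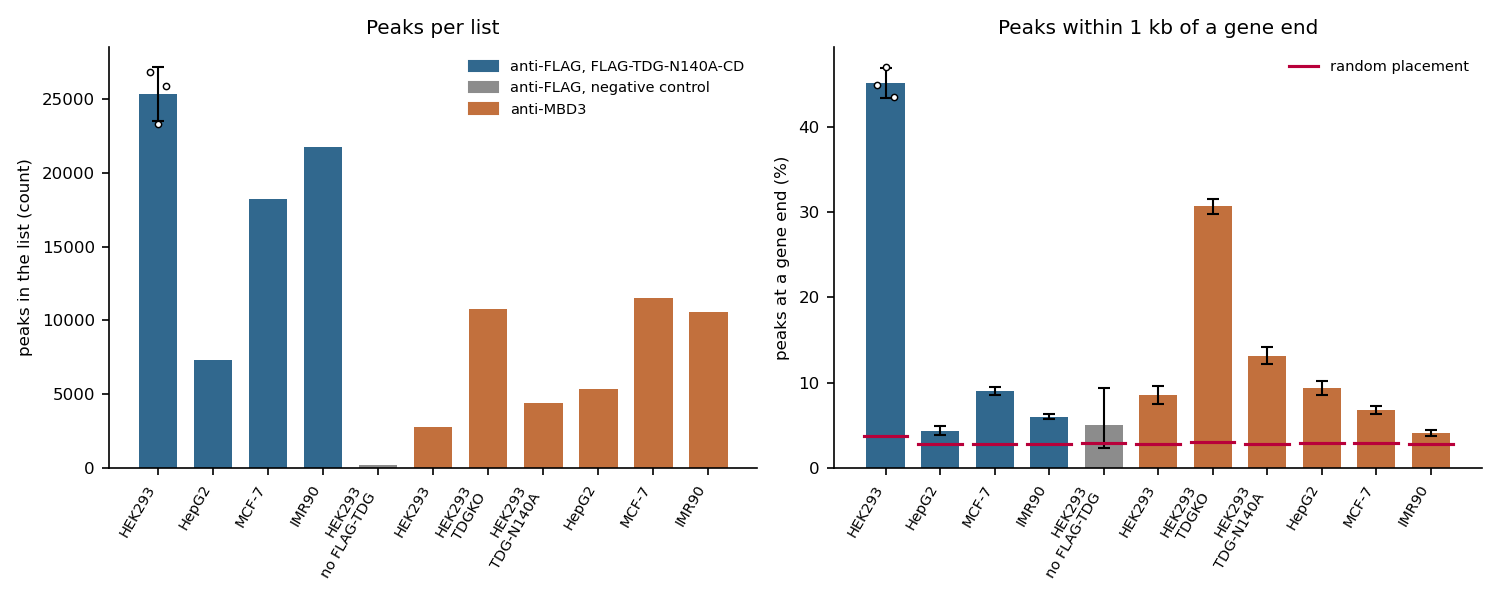
Number of peaks per list (left, count) and share of peaks within 1000 bp of a gene end (right, %) by cells and antibody. Bars for HEK293 FLAG-TDG are the mean of 3 libraries (points) with SD, the other right-hand bars carry exact binomial 95% intervals, and red lines mark random placement; the HEK293 FLAG-TDG and TDG-knockout MBD3 bars stand at 45.2% and 30.7%.

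Lists of genes for general cell functions had FLAG-TDG at most members in HEK293. Of 78 cytosolic ribosomal protein genes 76 were called (97.4%, percentile 100 among random gene lists of the same size), including RPS26 (fold 3.76 ± 0.612, SD, n = 3) and RPL18 (3.39 ± 0.699). Calls were made at 30 of 31 proteasome genes (96.8%, percentile 100), with PSMA7 at 5.15 ± 1.4 and PSMA6 the member without a call, and at 33 of 37 genes of respiratory complex I (89.2%, percentile 100), with NDUFS7 at 4.0 ± 0.655. DNA replication genes were called at 34 of 36 members (94.4%, percentile 100), among them the helicase factor CDC45 (3.52 ± 0.547) and the polymerase gene POLE (3.39 ± 0.322), with ORC1 and RPA3 not called. Immediate early genes, which respond to growth signals within minutes, were called at 26 of 28 members (92.9%, percentile 100), with FOS at 4.13 ± 1.02 and KLF4 at 4.38 ± 1.13, and ATF3 and IER3 not called. The base excision repair and cytosine oxidation list had 25 of 27 members called (92.6%, percentile 100), including the strand-break sensor PARP1 (3.54 ± 0.903), and lacked the glycosylases NEIL2 and SMUG1. NuRD subunit genes were called at 14 of 15 members (93.3%, percentile 99.6), with the deacetylase HDAC2 at 3.35 ± 1.19, the histone chaperone RBBP4 at 2.68 ± 0.378 and MTA1 not called. Of 477 numbered zinc finger genes 327 were called (68.6% against 62.3% of all genes, percentile 99.8).

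Genes with restricted expression had few FLAG-TDG calls in HEK293. Calls were made at 0 of 94 keratin-associated protein genes, 3 of 390 olfactory receptor genes (0.769%), 4 of 34 germline genes (11.8%), 4 of 30 lymphoid and myeloid markers (13.3%) and 6 of 34 hepatocyte markers (17.6%), and each of these lists stood at percentile 0 among random lists. The germline genes were MAEL, TDRD1, HORMAD1 and TEX14, and the blood markers CD8A, SPI1, BLK and LYZ. The 5 calls among 53 clustered protocadherin genes (9.43%) also stood at percentile 0, and the 9 calls among 30 luminal breast markers (30.0%) at percentile 0.015. Called members included the piRNA pathway gene MAEL (fold 3.50 ± 0.796, SD, n = 3), the hepatocyte transcription factor gene CEBPA (4.22 ± 0.902), the zinc transporter gene SLC39A6 (3.76 ± 0.356) and the T cell gene CD8A (2.93 ± 0.465). In between, within the central range of random lists, stood HOX genes (30 of 39, percentile 97.2; HOXD8 4.09 ± 0.454), replication-dependent histone genes (46 of 69, percentile 77.5; H4C3 3.41 ± 0.644) and the DNA methylation machinery (11 of 15, percentile 80.3; DNMT3B 3.04 ± 0.0845). The same held for the neural and renal developmental genes associated with HEK293 (13 of 25, percentile 14.9; NCAM1 3.78 ± 1.43), fibroblast markers (16 of 34, percentile 4.10; TWIST1 4.19 ± 1.72) and imprinted genes (13 of 29, percentile 2.83; GRB10 3.22 ± 0.371). In all, 15 of the 21 lists lay in the outer 2.5% on either side, 8 above and 7 below, and 14 did so when a peak anywhere in the gene counted and random lists were matched on gene length. With that wider definition NuRD subunits (percentile 93.5), zinc finger genes (96.4), luminal markers (4.98) and protocadherins (2.94) came inside the central range, and HOX genes (100), histone genes (100) and the neural and renal genes (99.5) went above it. Genes are not replicates, so no p-value was computed for a list.

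**Figure D2:**
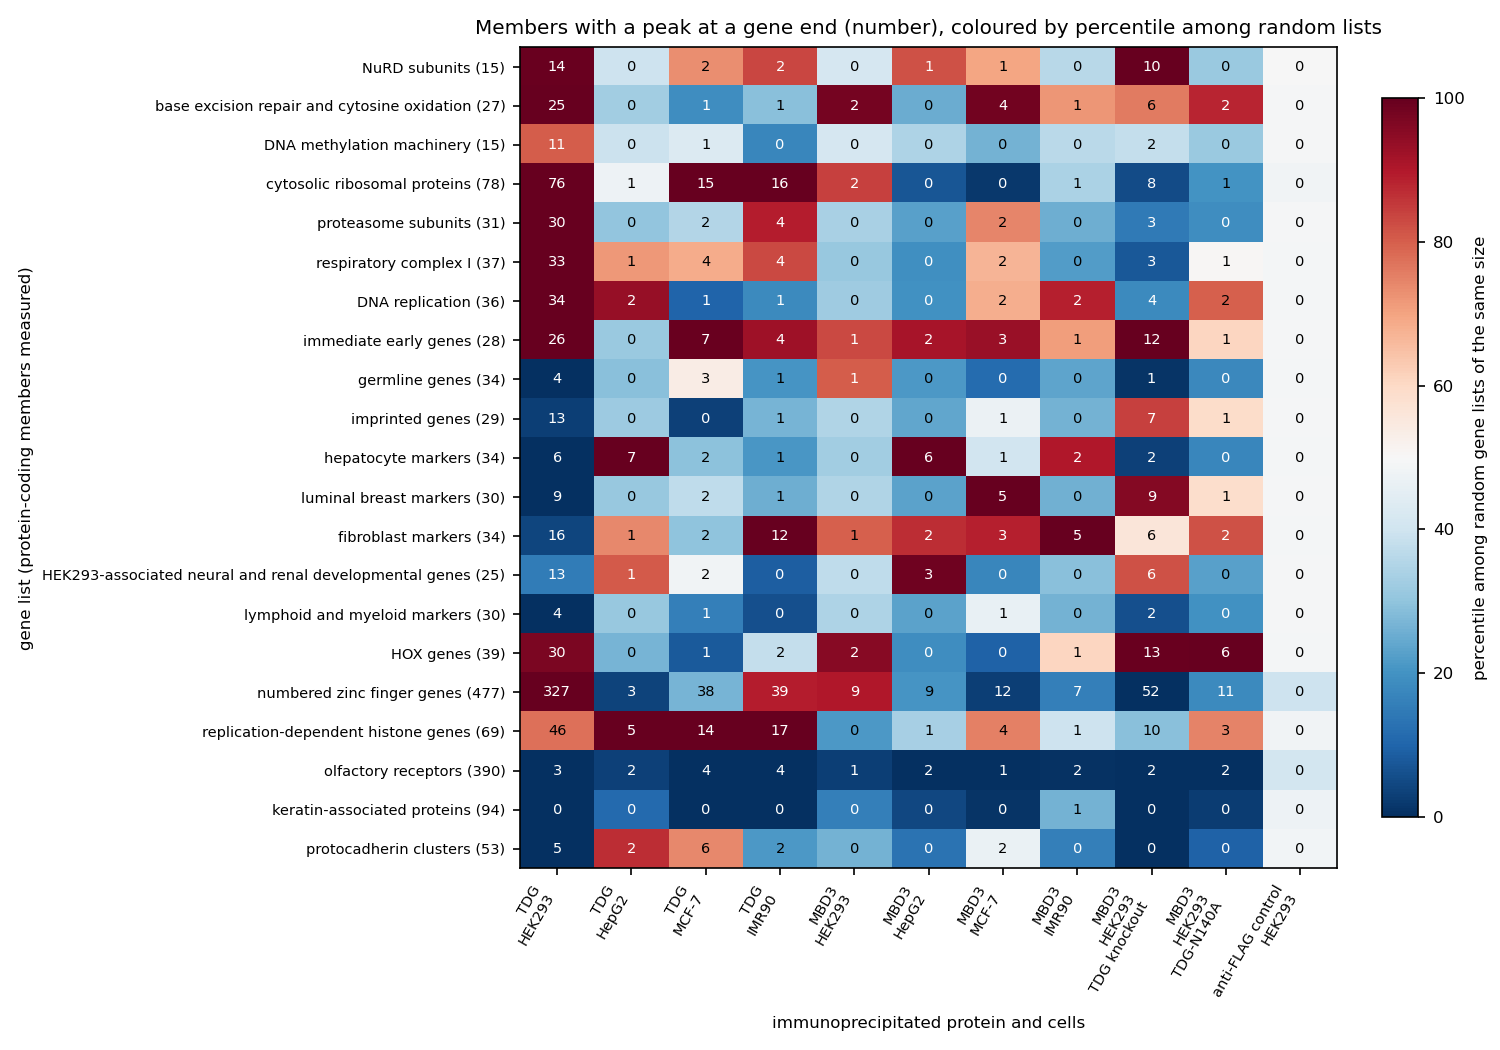
Members of each gene list with a peak at a gene end (numbers in cells) by immunoprecipitated protein and cells, coloured by percentile among 10000 random lists of the same size. Housekeeping lists are dark red in HEK293 FLAG-TDG, as with 76 of 78 ribosomal protein genes, and hepatocyte and fibroblast markers in HepG2 and IMR90.

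In the other lines FLAG-TDG marked fewer genes, and some of the lists it favoured were those of the line's own tissue. HepG2 had calls at 7 of 34 hepatocyte markers (20.6% against 1.58% of all genes, percentile 100), among them the fibrinogen genes FGA (fold 7.67) and FGG (4.47), the plasma glycoprotein gene AHSG (4.92) and the fatty acid carrier gene FABP1 (3.75). ALB and APOB, which encode albumin and apolipoprotein B, were not called there. IMR90 had calls at 12 of 34 fibroblast markers (35.3% against 6.74% of all genes, percentile 100), including the fibronectin gene FN1 (6.85), the matrix glycoprotein gene SPARC (6.73), the actin-binding gene CALD1 (5.53) and the collagen gene COL6A3 (4.38). In MCF-7 2 of 30 luminal breast markers were called at a gene end (FOXA1 2.90 and AGR2 4.93, percentile 37.5), and 12 when a peak anywhere in the gene counted (percentile 96.8). Ribosomal protein genes stood above random lists in MCF-7 (15 of 78, percentile 99.8; RPL14 5.77) and IMR90 (16 of 78, percentile 100; RPL35A 6.65). Histone genes did so in HepG2 (5 of 69, percentile 99.7; H2AC6 4.48), MCF-7 (14 of 69, percentile 99.9; H4C8 7.89) and IMR90 (17 of 69, percentile 100; H4C8 12.9), and immediate early genes in MCF-7 (7 of 28, percentile 99.6; KLF10 8.90). Histone genes lie in clusters and some share a peak, as H2AC6 and H2BC4 do, so their percentiles can be too extreme.

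At 58 genes FLAG-TDG was called in all 4 lines, where independent lists would share 1.17. After KMT2A, with folds of 4.83 in HepG2, 7.1 in MCF-7 and 8.19 in IMR90, the highest-ranked were EFCAB7 (HEK293 5.11 ± 1.12, SD, n = 3; HepG2 3.31, MCF-7 3.79, IMR90 6.25), the shared end of HYCC2 and the complex I gene NDUFB3 (HEK293 4.55 ± 1.00), FRA10AC1 (3.83 ± 0.332) and KMT5B. They were followed by the collagen pair COL4A5 and COL4A6 (4.70 ± 0.796), the mitochondrial ribosomal gene MRPL1 (3.68 ± 1.96), the translation initiation gene EIF4A2 (4.54 ± 1.23), the histone pair H2AC6 and H2BC4 (3.38 ± 0.817) and CTNND1 (4.97 ± 1.73), which encodes a cadherin-binding catenin. In IMR90, CTNND1 reached 8.76 and the histone pair 6.79. The lines called 317 genes in HepG2, 1761 in MCF-7 and 1350 in IMR90, and HEK293 also called 65.6%, 88.2% and 79.0% of these, against 62.3% of all genes. HepG2 and MCF-7 shared 110 genes where independent lists would share 27.9, HepG2 and IMR90 116 against 21.4, and MCF-7 and IMR90 408 against 119. The number shared by all 4 lines was 13 with peaks of −log10 q of at least 5, 38 with a window of 500 bp and 18 with equal numbers of top peaks, where independent lists would share 0.0948, 0.460 and 0.0527.

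Other genes were called in 1 line and in none of the other 3. For HEK293 these numbered 10138, and the top of those called in all 3 of its libraries were the pair POLR2J3 and LOC124901712 (fold 3.22 ± 0.421, SD, n = 3), the threonyl-tRNA synthetase gene TARS3 (4.61 ± 1.11), the protocadherin gene PCDH9 (3.07 ± 0.448) and the netrin receptor gene UNC5A (5.93 ± 0.183). For HepG2 they numbered 71, led by the acyl-CoA synthetase genes ACSM2A (9.97) and ACSM2B (8.05), FGA and SMLR1 (6.95). The peak at FGA lay from 154590558 to 154590973 on chromosome 4, at one end of the gene. For MCF-7 they numbered 154, led by ARHGEF38 (11.2), the DNA end resection gene RBBP8 (11.7), UNC13C (11.7) and the cytokine gene IL19 (10.1). For IMR90 they numbered 225, led by SMIM21 (11), FRMD6 (10.7), the carboxypeptidase gene CPA4 (8.54) and SIRPB2 (6.85). Differences between lines at single genes were not tested.

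Many MBD3 peaks lay where FLAG-TDG was found in the same line, the question that the series title raises about TDG and MBD3/NuRD. Of the FLAG-TDG genes named above for single lines, MBD3 was also called in the same line at PCDH9 (fold 4.49) in HEK293, at ACSM2A (8.12), ACSM2B (10.8) and SMLR1 (5.80) in HepG2, at ARHGEF38 (3.98), RBBP8 (14.3), UNC13C (6.25) and IL19 (10.4) in MCF-7, and at SMIM21 (11.8), FRMD6 (8.44) and CPA4 (10.3) in IMR90. The pair POLR2J3 and LOC124901712, TARS3 and UNC5A in HEK293, FGA in HepG2 and SIRPB2 in IMR90 had no MBD3 peak in the same line. Of all MBD3 peaks, 62.0% overlapped a FLAG-TDG peak of the same line in IMR90 (exact binomial 95% interval 61.1 to 62.9), 53.5% in HEK293 (51.6 to 55.4; 1488 of 2781), 50.6% in MCF-7 (49.7 to 51.5) and 33.0% in HepG2 (31.7 to 34.3). Randomly placed MBD3 peaks overlapped in 0.568%, 1.05%, 0.488% and 0.219% of cases. In the other direction 30.1%, 6.60%, 32.1% and 24% of FLAG-TDG peaks or regions had an MBD3 peak. In HepG2, MCF-7 and IMR90 both lists share an input library, per the labels, and a simulation of lists with a common input and no enrichment gave overlaps of 0.186%, 0.146% and 0%. The simulation left out real enrichment, so it sets no bound on what a common input could give.

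Most of this overlap lay away from gene ends. In HepG2, MCF-7 and IMR90 the MBD3 peaks on FLAG-TDG were at a gene end in 4.59%, 4.84% and 2.98% of cases and the other MBD3 peaks in 11.6%, 8.78% and 5.90%. HEK293 showed the opposite order, 12.9% on FLAG-TDG regions and 3.46% off them. Where the peaks overlapped, the summits of both proteins were a median of 65 bp apart in HepG2, 37 bp in MCF-7 and 62 bp in IMR90, against 137, 114 and 137 bp for random points in the same peaks. HEK293 was not measured, and the measured lines have a common input. The distances thus cannot tell common occupancy from a common input. The HEK293 share of MBD3 peaks on FLAG-TDG depended on the number of FLAG-TDG peaks. It was 9.53% with equal numbers of top peaks. With FLAG-TDG lists thinned to the MCF-7 floor in a single draw, an alternative chosen after the data were seen, it was 30.9%.

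The overlap of peaks followed the cell line, while the gene-end odds ratio did so for MBD3 of 3 of the 4 lines. MBD3 peaks overlapped FLAG-TDG of their own line in 49.8 ± 12.2% of cases (SD, n = 4 lines) and FLAG-TDG of another line in 12.5% on average, with 20.9% the highest single value. Among 12939 genes with FLAG-TDG at an end in some but not all lines, the log2 odds ratio of MBD3 and FLAG-TDG calls was 3.85 in HepG2, 3.83 in IMR90 and 2.56 in MCF-7, and −0.09 in HEK293. The HEK293 value was the highest for HEK293 FLAG-TDG, whose odds ratios with MBD3 of HepG2, MCF-7 and IMR90 were −2.08, −1.24 and −3.48, but the lowest for HEK293 MBD3, which gave 1.46, 1.45 and 1.78 with FLAG-TDG of HepG2, MCF-7 and IMR90. These low values follow in part from leaving out genes called in all lines or none, since HEK293 called 62.3% of all genes. The unmatched pairs without a HEK293 list gave 0.28 to 1.75. The mean was 2.54 for matched lines and 0.26 for unmatched ones, and an exact one-sided test over the 24 pairings of the lists gave p = 0.0417, the smallest p that 24 pairings can give. The same exact one-sided test on the peak overlap also gave p = 0.0417, and adjustment over both tests by Benjamini-Hochberg leaves 0.0417. In HepG2, MCF-7 and IMR90 the matched lists have a common input, per the labels, while lists of different lines do not. Neither test can thus tell common occupancy from a common input. Genes with both proteins numbered 86 in HepG2 (7.88 for independent lists), 341 in MCF-7 (73.6), 210 in IMR90 (28.8) and 216 in HEK293 (151). Both proteins need not share an end, and at POLK and CYB561 in HEK293 they lay at opposite ends.

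**Figure D3:**
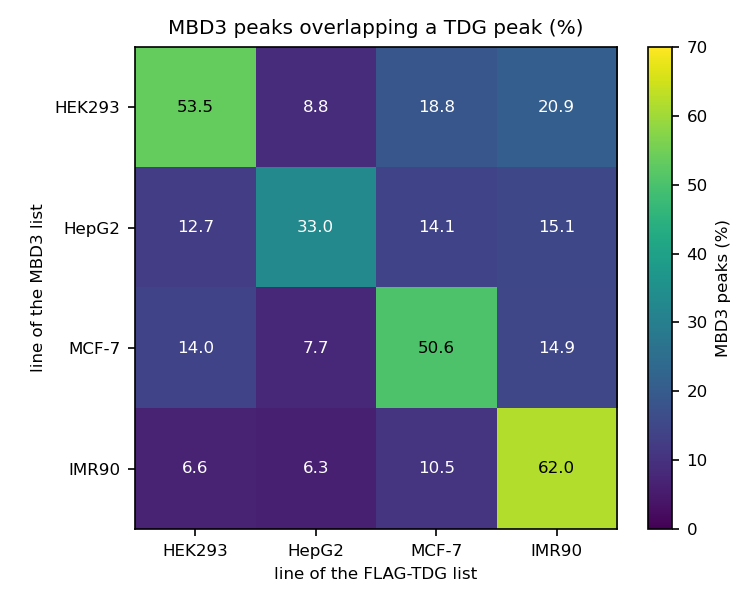
Percent of MBD3 peaks of each line (vertical axis) that overlap a FLAG-TDG peak of each line (horizontal axis), with 1 MBD3 list per line. Overlap within a line, on the diagonal, is 33.0% to 62.0%, and between lines it is at most 20.9%.

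MBD3 itself was called at the ends of few genes, and at 9 of them in all 4 lines, where independent lists would share 0.00539. The highest-ranked was TDRD7, which encodes a tudor-domain protein of germ granules and spans 97412096 to 97496125 on chromosome 9. Its MBD3 peak had folds of 11.1 in HEK293, 18.1 in HepG2, 15.8 in MCF-7 and 6.10 in IMR90, and FLAG-TDG in HEK293 had 3.78 ± 0.984 (SD, n = 3) there. The others, with their folds in HEK293, were KLHDC9 (8.56), RNF187 (4.95), BRINP3 (8.59), the Rho inhibitor gene ARHGDIA (3.00), EFCAB7 (3.26), the unfolded protein response gene ATF6 (3.75), the Wnt coactivator gene BCL9 (4.86) and IQGAP2 (2.84). At BRINP3 the HepG2 peak lay at the lower-coordinate end and the HEK293, MCF-7 and IMR90 peaks at the higher. The lines thus did not all share a site there. The count of genes in all 4 lines was 5 with a window of 500 bp and 4 with equal numbers of top peaks.

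Per line MBD3 was called at 243 genes in HEK293, 498 in HepG2, 837 in MCF-7 and 428 in IMR90, and the share of its peaks at gene ends was 8.53% (exact binomial 95% interval 7.51 to 9.64), 9.37% (8.59 to 10.2), 6.80% (6.34 to 7.28) and 4.10% (3.73 to 4.49). As with FLAG-TDG, HepG2 calls favoured hepatocyte markers (6 of 34, percentile 100), with the plasma protein genes HP at a fold of 9.19 and HPX at 6.33, and also the neural and renal genes ASCL1, SIX1 and SALL4 (3 of 25, percentile 98.5). IMR90 calls favoured fibroblast markers (5 of 34, percentile 100), with the protease inhibitor gene SERPINE1 at 4.04 and COL6A3 at 4.17. MCF-7 calls favoured luminal breast markers (5 of 30, percentile 99.6), with the transcription factor gene SPDEF at 4.48 and the estrogen-responsive TFF1 and GREB1 at 4.59 and 3.61. MCF-7 also had MBD3 at 4 of 27 base excision repair and cytosine oxidation genes (percentile 98.3), NTHL1 (3.43), TET3 (3.08), PARP2 (3.29) and GADD45G (2.34), and HEK293 at 2 of 27 (percentile 97.8), the glycosylase gene NEIL3 (5.89) and PARP2 (2.82). Both came inside the central range, at percentiles 72.2 and 89.2, when a peak anywhere in the gene counted and random lists were matched on gene length. In HEK293 it was the 1 list of 21 outside the range, about what chance gives. Ribosomal protein genes, rich in FLAG-TDG calls, had none for MBD3 in MCF-7 (0 of 78, percentile 1.82).

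Genes with MBD3 in 1 line and none of the other 3 were led in HEK293 by TEX19 (fold 10.1), the granzyme gene GZMM (7.11), NEIL3 and the growth-responsive transcription factor gene JUND (4.41). HepG2 was led by the homeobox gene MEIS1 (8.24), C4orf36 (14.8), the tubulin gene TUBA1A (8.68) and CBLC (7.38). MCF-7 was led by the chromatin reader gene ZMYND8 (2.66), ASPSCR1 (6.51), the syntaxin gene STX16 (2.93) and LOC124900276 (4.86). IMR90 was led by the retinoic acid hydroxylase gene CYP26C1 (6.36), the shared end of CRHBP and S100Z (6.81), ZHX3 (12.0) and the heme transporter family gene FLVCR2 (12.7). These sets numbered 121, 343, 658 and 288 genes.

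The HEK293 genotypes address whether MBD3 occupancy changes with TDG. MBD3 peaks were more numerous in TDG knockout: there were 10799 peaks against 2781 in the wild type, and 3403 called genes against 243. Of the wild-type genes 208 (85.6%) were called in the knockout, where independent lists would share 41.3. TDRD7 had a fold of 15.7 in the knockout and 13.3 in TDG-N140A against 11.1 in the wild type, GZMM 8.39 and 6.70 against 7.11, NEIL3 8.09 and 9.93 against 5.89, and JUND 9.20 and 5.80 against 4.41. TEX19 had lower folds of 6.95 and 8.29 against 10.1 in the wild type, and 2 genes with MBD3 in all 4 lines had lower folds in the knockout, KLHDC9 (6.64 against 8.56) and BRINP3 (4.43 against 8.59), with 11.8 and 8.73 in TDG-N140A. Folds depend on the depth of a library, so these differences are only described and were not tested. Of the wild-type peaks 63.6% (exact binomial 95% interval 61.8 to 65.4) were called in the knockout and 49.0% (47.1 to 50.9) in TDG-N140A, against 0% and 0.217% in simulated lists with a common input and no enrichment. That simulation left out real enrichment, so it sets no bound on what a common input could give. The backgrounds of the wild-type list and of the knockout and TDG-N140A lists correlated at r = 0.996 for both pairs, across peak summits that are not independent replicates. With equal numbers of top peaks the order turned round, with 36.5% in the knockout and 41.2% in TDG-N140A.

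MBD3 peaks lay at gene ends more often in TDG knockout than in the wild type, although most knockout peaks lay elsewhere. Of 9029 knockout peaks that no wild-type peak overlapped 34.4% were at a gene end, against 11.4% of those overlapped. The share of MBD3 peaks at gene ends was 30.7% in the knockout (exact binomial 95% interval 29.8 to 31.6), 13.1% in TDG-N140A (12.1 to 14.2) and 8.53% in the wild type (7.51 to 9.64). Of 3195 genes called in the knockout and not in the wild type, 3101 (97.1%) had FLAG-TDG, against 88.9% of the wild-type MBD3 genes and 62.3% of all genes, and of 447 such genes in TDG-N140A 413 (92.4%) did. Both genotypes called 362 genes that the wild type did not, led by the glucocerebrosidase gene GBA1 (fold 7.63 in knockout, 5.25 in TDG-N140A), the RNA polymerase III gene POLR3H (5.43 and 3.13), the replication licensing gene CDT1 (5.88 and 4.21), the potassium channel gene KCNJ4 (4.81 and 3.87), the shared end of KLLN, MLDHR and the tumour suppressor gene PTEN (6.20 and 4.73) and FHIP2A (8.20 and 3.84). The PTEN peak in the knockout ran from 87863273 to 87863833 on chromosome 10. In the other direction 35 wild-type genes were not called in the knockout, led by SHROOM3 (8.58), the shared end of ANKDD1B and the translesion polymerase gene POLK (7.49), LOC124905556 (8.37), GAGE12D (7.71), CYB561 (5.94) and CNIH4 (7.42), the last also a peak of the anti-FLAG control.

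NuRD genes themselves were among the places where MBD3 was called in the knockout, with 10 of 15 subunit genes (66.7% against 17.0% of all genes, percentile 100), including CHD3 (fold 3.62), CHD5 (4.59), CDK2AP1 (3.58), RBBP7 (3.11) and CHD4 (2.43). The wild type called 0 of the 15 and 1.21% of all genes, within the central range of random lists (percentile 41.5), so its 0 is no contrast. Immediate early genes were called at 12 of 28 members (percentile 99.9), with DUSP1 at 3.22 and KLF10 at 2.95, and HOX genes at 13 of 39 (percentile 99.5), with HOXA1 at 5.53 and HOXD8 at 4.04. HOX genes were also above random lists in TDG-N140A, with 6 of 39 (percentile 100), where HOXC4, HOXC5 and HOXC6 share a peak of fold 5.30. That peak counted once for each of these genes. Random lists draw scattered genes, so the percentiles of clustered lists such as HOX genes can be too extreme. Zinc finger genes were called at 52 of 477 members in the knockout (percentile 0.015), below random lists, although 327 of them carried FLAG-TDG.

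Of all MBD3 peaks 63.3% (exact binomial 95% interval 62.3 to 64.2) lay on the reproducible HEK293 FLAG-TDG regions in the knockout and 51.5% (49.996 to 53.0) in TDG-N140A, against 53.5% (51.6 to 55.4) in the wild type, and randomly placed peaks did so in 1.12% and 1.05% of cases. With equal numbers of top peaks the shares were 37.6% in the knockout, 12.6% in TDG-N140A and 9.53% in the wild type. The number was set by each MBD3 list, at 10799, 4425 and 2781 peaks. The FLAG-TDG lists were cut to these sizes too, so the shares do not compare genotypes at an equal number. Each genotype had 1 library, so the differences between genotypes have no replicate spread to be judged against and were not tested. The knockout list also had a background floor 1.23 times that of the wild type; thinned to the wild-type floor it kept 9712 peaks, 3.49 times the wild-type number, of which 30.4% lay at gene ends.

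**Figure D4:**
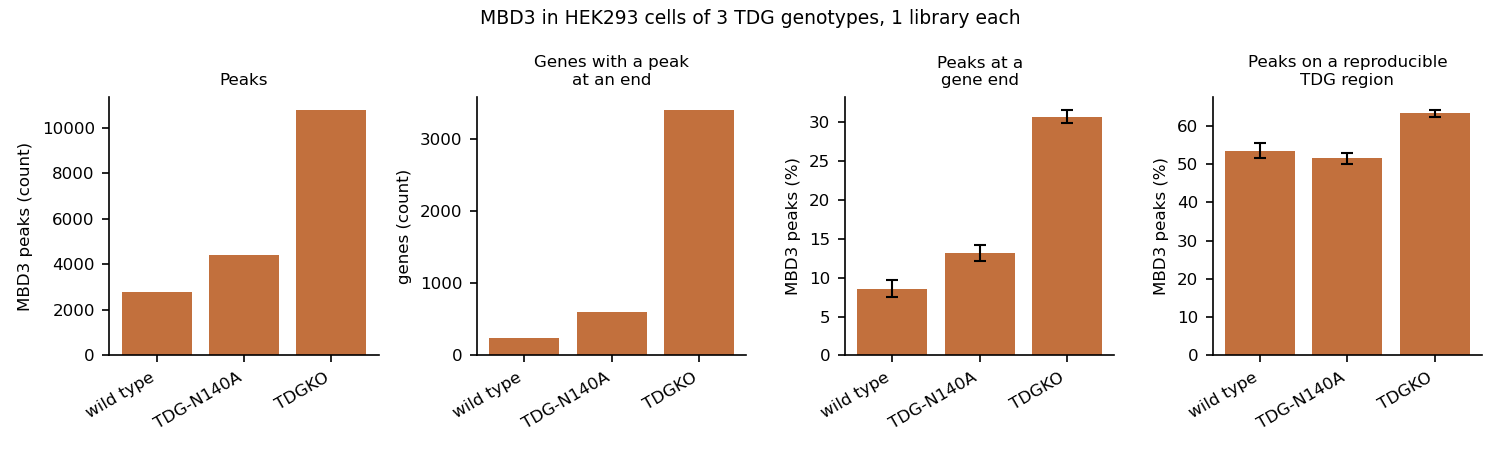
MBD3 in HEK293 by TDG genotype, 1 library each: number of peaks, number of genes with a peak within 1000 bp of an end, share of peaks at a gene end (%) and share on a reproducible FLAG-TDG region (%). Error bars are exact binomial 95% intervals; all 4 measures are highest in the knockout, with 10799 peaks and 3403 genes.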

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

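The predictions for library preparation, over-representation in the input, a common input in HEK293 and regional copy number were written only after the results were seen. Those for the other tests were written before the tests. The depth and peak-width tests rest on the thinned lists and trimmed peaks, which were themselves chosen after the data were seen. A signal in sequence outside the 24 chromosomes that the comparisons used was a mean of 24 ± 3.61 (SD, n = 3) HEK293 FLAG-TDG peaks on 2 unplaced contigs that carry 45S ribosomal RNA genes (RNA45SN5 and RNA45SN4), where the anti-FLAG control had 0. Of these, 7.33 ± 4.04 lay within the 45S genes, and 1.32 ± 0.643 of the 24 were left at the floor of the control. IMR90 FLAG-TDG had 27 peaks on these contigs, HepG2 and MCF-7 1 each, and MBD3 0 in wild-type HEK293, 0 in the knockout and 1 in TDG-N140A.

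The share of FLAG-TDG peaks at gene ends was 45.2 ± 1.79% in HEK293 and at most 9.02% in the other lines. The tables argue against greater depth in HEK293, as far as the floor measures it, since lists thinned to the floors of the other lines had at least 52.9% of peaks at gene ends, and against peak width, since peaks trimmed to 300 bp had 43.9%. A difference in library preparation remains open, because the shortest peaks, which follow fragment length, were 304 bp or longer in HEK293 FLAG-TDG and 186 to 221 bp in the other 10 lists, so that line and preparation cannot be told apart. Recovery of chromatin that is already over-represented in the input, such as open gene ends, may also account for part, because HEK293 peaks with a local background under 2 times the floor lay at a gene end in 4.47% of cases, close to the 2.39% to 3.25% of the other lines, while those above lay there in 54.7% against at most 19.7%, and this cannot be told apart. A difference in TDG binding between the lines also remains open.

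MBD3 had 10799 peaks in TDG knockout and 2781 in wild-type HEK293, and 97.1% of the genes called in the knockout alone of the pair had FLAG-TDG, against 88.9% of wild-type MBD3 genes. Depth, as far as the floor measures it, is excluded as the whole cause, because 9712 peaks were left when the knockout list was thinned to the wild-type floor. The labels name no input for MBD3 in HEK293, so the library behind the local background is not known. Wild-type and knockout backgrounds correlated at r = 0.996 across shared summits, with a median ratio of 0.816 against 0.814 for the floors. Both lists may thus have a common background library. The local background, relative to the floor, was 4.45 times as high under knockout peaks as under wild-type peaks. If it came from an input, recovery of chromatin already over-represented there, such as open gene ends, may account for part of the gain. With 1 library per genotype this cannot be told apart from an effect of TDG loss, which stays open and untested.

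Between 33.0% and 62.0% of MBD3 peaks lay on FLAG-TDG of the same line. MBD3 peaks moved by up to 50 kb fell on FLAG-TDG in at most 3.56% of cases, which argues against regional peak density as the cause. Moves cannot show whether a copy gain led both lists to call the same positions, so regional copy number is not excluded. In HEK293 the control held 3.10% of the MBD3 peaks on FLAG-TDG regions that its floor could show. That argues against antibody-independent recovery there. It does not exclude such recovery, since the control is unreplicated and used another antibody than the MBD3 list. A common input gave at most 0.186% of such overlap in simulated lists with no enrichment; the bound set beforehand, 10% in every line, was met, but the simulation left out real enrichment, on which errors of a common input act too, so that bound was wrongly set and excludes nothing. The backgrounds correlated across summits at 0.989 to 0.994 in the lines with a common input, part of the excess there may come from it, and this cannot be told apart. In HEK293, where the labels name inputs for FLAG-TDG and none for MBD3, the correlation was at most 0.814, below the lines with a common input, which argues against a common input there, and common occupancy of open chromatin or a TDG and MBD3/NuRD interaction stay open and untested.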

How the results depend on the processing

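The thinned lists, the trimmed peaks and the count of peaks anywhere in a gene were chosen only after the data were seen; all other alternatives were among the choices made before the data were examined. Of 84 alternative values 48 held and 36 changed. Counts held within a fixed ratio, shares inside the exact binomial interval, the gene-end share within its replicate SD and line matching by its p-value. A change from 21962 to 15623 regions thus held, while 63.6% to 61.3% of wild-type peaks in the thinned knockout did not. The tally is therefore no measure of robustness. Only the 8 values of the line matching have a sign that could reverse, and 0 of them did. The order of knockout and TDG-N140A in calls of wild-type MBD3 peaks turned round with equal numbers of top peaks. The line matching held in all 8 of its alternatives (mean log2 odds ratio 2.31 to 2.96, exact one-sided permutation p = 0.0417 in each), reproducible HEK293 FLAG-TDG regions ranged from 15623 to 21906, and all 12 values held without peaks that overlap a control peak, which tests little since this removed 56 of 21962 HEK293 FLAG-TDG regions. No paired analysis was possible because replicate numbers are shared only with input libraries, to which no peak list belongs. Alternatives on the 5′ end and CpG-matched random lists were not run, for want of strands and sequence. Depth, known through the background floor alone, limits every comparison of peak numbers between lists.

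With −log10 q of at least 5 the share of HEK293 FLAG-TDG peaks at gene ends was 52.1%, 13 genes had FLAG-TDG in 4 lines, MBD3 overlapped FLAG-TDG in 25.7% of HepG2, 57.6% of IMR90 and 59.0% of knockout peaks, and 68.6% and 52.9% of wild-type MBD3 peaks were called in knockout and TDG-N140A. With an overlap of 50% MBD3 overlapped FLAG-TDG in 31.0% (HepG2), 49.1% (MCF-7), 59.4% (IMR90) and 62.3% (knockout). With a window of 500 bp the gene-end share was 42.1%, and 38 genes had FLAG-TDG and 5 MBD3 in 4 lines. With equal numbers of top peaks these counts were 18 and 4, MBD3 overlapped FLAG-TDG in 9.53% (HEK293), 28.1% (HepG2), 40.2% (MCF-7), 42.1% (IMR90), 37.6% (knockout) and 12.6% (TDG-N140A), and wild-type peaks were called in 36.5% (knockout) and 41.2% (TDG-N140A). For the overlaps with FLAG-TDG the numbers were equal within each comparison and not between them. Leaving out a HEK293 replicate gave 40.9% to 43.5% (HEK293), 54.5% to 55.8% (knockout) and 41.1% to 42.4% (TDG-N140A), where a region then needed both other libraries. In a single draw each, lists thinned to the MCF-7 floor gave 53.6% at gene ends and 30.9% overlap in HEK293, and the thinned knockout 61.3% of wild-type peaks. Stricter lists hold fewer peaks by construction; otherwise the cause was not tested.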

Other observations

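Peaks of both proteins were spread unevenly over the chromosomes, with similar profiles for both in HepG2, MCF-7 and IMR90. In HepG2 chromosome 20 held 4.05 times as many FLAG-TDG peaks and 2.71 times as many MBD3 peaks as its length predicts. Chromosome 14 held 2.19 and 1.58 times, chromosome 2 held 2.17 and 1.64 times and chromosome 16 held 2.10 and 2.09 times as many. On chromosome 19 they differed, at 0.324 for FLAG-TDG and 1.06 for MBD3. In MCF-7 chromosome 20 held 2.77 and 3.25 times and chromosome 17 1.78 and 1.93 times as many, with chromosome 18 at 0.305 for FLAG-TDG. In HEK293 the gene-dense chromosomes 19 (2.82 times) and 17 (1.87 times) led for FLAG-TDG, and chromosome 19 held 2.00 times as many MBD3 peaks as its length predicts in TDG knockout and 1.21 times in the wild type. The chromosome profiles of FLAG-TDG and MBD3 correlated at r = 0.920 in HepG2, 0.973 in MCF-7, 0.967 in IMR90 and 0.373 in HEK293, and HEK293 FLAG-TDG with knockout MBD3 at 0.799, across 23 chromosomes, which are not independent replicates. In HepG2, MCF-7 and IMR90 both lists have a common input, per the labels, and copy number was not measured. These correlations thus do not show common occupancy.

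The anti-FLAG control shared sites with unrelated libraries. Of its 216 peaks 41.2% overlapped HepG2 FLAG-TDG, 39.8% MCF-7 FLAG-TDG, 35.6% IMR90 FLAG-TDG and 35.6% wild-type HEK293 MBD3, while 26.9% overlapped HEK293 FLAG-TDG regions, and 18.1% lay outside the 24 chromosomes, against 0.277 ± 0.0229% (SD, n = 3) of HEK293 FLAG-TDG peaks. On the contigs with 45S ribosomal RNA genes MBD3 had 9 peaks in HepG2, 3 in MCF-7 and 4 in IMR90. TET2 had a FLAG-TDG peak in IMR90 (fold 5.14) and TET1 an MBD3 peak in TDG knockout (2.96).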
